A study of Mus musculus with 15 samples.

How the data were processed

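RNA of 15 samples was measured on one-colour Agilent arrays labelled with Cy3, 1 array per sample: 4 host kidney, 4 host liver, 4 neo-liver and 3 control liver. Per the file headers, the scanner files hold intensity values written by Agilent Feature Extraction 10.10.1.1, and the processed signal used here had been background-subtracted and detrended within each array and not scaled between arrays. The series table was deposited as log2 values, which lay within 0.01 of the log2 processed signal minus 1 constant per array, near its 75th percentile, for 99.8% of the probes of an array. The software of that step is not given in the sources used here.

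Spots of one probe were averaged, giving 55681 probes from 59305 spots, and the log2 processed signal minus its 75th percentile on the array was analysed. A probe was kept if it was well above background, by the scanner software's own call, on every array of at least 1 group. This kept 34992 probes, of which 20391 had a gene symbol through a RefSeq accession and 14601 had none and were not tested. The array design was annotated on mouse build mm9 and the symbols come from a later release, so no positions are given. For each symbol the probe with the highest mean over all arrays was taken, which left 15622 genes, 4004 of them with over 1 kept probe. Probes of a gene are said to disagree where the differences of its kept probes had opposite signs. No spot was saturated. The number of arrays and the signal over background limit the precision, since an array has no read depth.

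All arrays entered 1 limma fit with a mean per group (R 4.3.3, limma 3.58.1, data.table version 1.17.8, statmod 1.5.0), and differences between groups were tested with limma's moderated test. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. Where all arrays of 1 group were below background, a difference is given as "at least N-fold" against, on each array of that group, the higher of its own signal and the lowest signal called above background, and where both groups were below it no fold is given. Gene lists were tested with limma's camera, which compares a list's genes with all other genes, with a preset correlation of 0.01 between genes and, beside it, with an estimated correlation. Camera p were adjusted over the 37 lists of a comparison. Of 734 members of 38 lists, 687 were tested. The 4 genes of the Y-linked list were above background on 0 of 15 arrays. Several members are shared between lists or made by both organs, for example bile duct markers that kidney tubule also makes. With the preset correlation, 27, 20, 15 and 16 lists were called in the order of the comparisons in the text. With an estimated correlation, 9, 1, 3 and 0 of these held, and the text gives that adjusted p beside the others.

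The comparisons, the lists, the rule for naming genes and the alternatives were fixed before the data were examined, apart from those stated here. Named genes are the 8 with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap, without predicted gene models and receptor segments, then 18 lead genes, then called members of each list. Some genes that this rule names are not given in the text. The rule allowed up to 3 members in the main direction and 2 in the other. Taking only the first 2 of each called list in the main direction was decided after the values were seen. The alternatives with mouse as a random block and without genes below background in both groups, and the kidney zone markers, were also added after seeing the data. For normexp background correction the files held no mean spot signal, so median spot and median local background signals of all spots, 3671 control spots per array included, were used with an offset of 50.

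The kidney share of an array is the median, over kidney epithelium markers at least 8-fold higher in host kidney than in control liver, of its signal above control liver as a percentage of that of host kidney, on the linear scale. The alternative that subtracts it removes this share of the mean host kidney signal from each neo-liver array before log2. Organ-enriched genes differed by at least 3 on the log2 scale between the host organs. Overlap between comparisons that share the 3 control livers was set against 100 simulations of unchanged groups. Host kidney arrays filled 1 slide, neo-liver and control liver arrays another, and host liver arrays 1 and 2 and arrays 3 and 4 one slide each. Residuals of the 3 host tissues were best correlated within the same replicate number in 4 of 4 numbers for each pair of tissues (r across genes 0.179 to 0.577), so numbers were taken to stand for mice and used as a block in alternatives. The residual correlation was 0.348 within mice and 0.0371 within slides. Control livers only share numbers with the hosts.

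Other alternatives were quantile normalization, median centring, the deposited log2 values, no filter and a stricter filter on dim probes, the mean of all probes, array weights, a variance trend with robust estimation, fits of 2 groups alone, a threshold of 1 on the log2 scale and leaving out each array in turn. In arrays simulated from each gene's mean and residual spread, 2-fold changes were recovered in 56% to 75% and 4-fold changes in 86% to 95% of 100 genes, with 2 to 14 unchanged genes called. The changed list was called in all 4 comparisons, beside 0 or 1 others. Host liver mixed with 10%, 20%, 30% and 50% of host kidney signal, which sets the scale, gave shares of 10.6%, 20.6%, 26.6% and 47.2%. This checked arithmetic only. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.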

Results

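RNA levels were measured in 15 tissue samples of female FVB/N mice, with 1 microarray per sample. Mice of the transplant arm, called hosts here, had received monocrotaline, a plant alkaloid that injures liver endothelium and hepatocytes, at 70 mg/kg in 2 doses 2 weeks apart, and then 1000000 hepatocytes beneath the capsule of the kidney. The donor mice carried a human antitrypsin transgene. At 250 to 300 days, when the hosts were 48 to 55 weeks old, 4 samples each were taken of the kidney (host kidney), the injured liver (host liver) and the ectopic liver tissue dissected out of kidneys (neo-liver). Livers of 3 normal mice aged 20 weeks served as control liver. The title of the series concerns liver formation in the kidney and the recruitment of non-parenchymal cells, so the markers of liver cell types are given for each comparison. The 75th percentile of the signal lay between 416 and 676 on the neo-liver arrays, 561 and 874 on the host kidney arrays, 287 and 448 on the host liver arrays and 389 and 424 on the control liver arrays. Mean shares of probes well above background were 59.0%, 65.7%, 49.8% and 54.4% in that order. The number of arrays, 3 or 4 per group, limits the precision of each value. All comparisons cover the same 15622 genes, and differences are log2 differences with their standard error (SE) and limma's adjusted p. For gene lists, the p of limma's camera test adjusted over the lists of a comparison is given as list adjusted p.

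Neo-liver against host kidney asked what the ectopic tissue expressed that the surrounding organ did not. Alb, which encodes albumin, rose by 10.23 ± 0.21 (SE, 4 against 4 arrays, adjusted p = 1.32e-13), and Hpx, which encodes the haem carrier hemopexin, by 13.05 ± 0.36. The Kupffer cell marker Clec4f was at least 1061-fold higher, the sinusoidal endothelial scavenger receptor gene Stab2 rose by 6.40 ± 0.20, and Lrat, whose enzyme stores vitamin A in stellate cells, by 3.24 ± 0.23. Umod, which encodes the uromodulin of the thick ascending limb, fell by 3.33 ± 0.48, and Slc34a1, a phosphate transporter gene of the proximal tubule, fell by 1.23 ± 0.35. In all, 3622 genes were higher and 4608 lower in neo-liver, of which 2027 and 2102 differed at least 2-fold.

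Of the plasma protein genes 26 of 27 rose (26 adjusted over the list alone, list adjusted p = 3.97e-26), and Apoa1, for the main protein of high-density lipoprotein, rose by 13.80 ± 0.43. Acute phase genes, of which 19 of 19 rose (19 adjusted over the list alone, list adjusted p = 3.00e-15), included Saa2, at least 4200-fold higher, and Hamp, the gene of the iron hormone hepcidin, at 13.65 ± 0.85. Of the cytochrome P450 genes of drug metabolism 19 of 20 rose (19 adjusted over the list alone, list adjusted p = 1.86e-15). Cyp2c50 changed by 13.32 ± 0.87 and Cyp2c39 by 13.21 ± 0.67. Among liver transcription factors 14 of 16 rose (14 adjusted over the list alone, list adjusted p = 9.56e-09), led by Foxa2 (8.89 ± 0.20) and Foxa3 (at least 195-fold), whereas Hnf4a, which kidney tubule also uses, differed by 0.24 ± 0.12 (adjusted p = 0.114). Of the bile acid genes 15 of 20 rose and 2 fell (15 and 2 adjusted over the list alone, list adjusted p = 2.58e-09): the uptake transporter gene Slco1b2 rose by 13.22 ± 0.59, and Cyp7a1, for the rate-limiting enzyme of bile acid synthesis, was at least 503-fold higher. Of the urea cycle and amino acid genes 14 of 18 rose (14 adjusted over the list alone, list adjusted p = 9.00e-09, adjusted p = 0.147 with an estimated correlation), among them Otc, at least 1473-fold, and Arg1, at least 2382-fold. For gluconeogenesis 7 of 11 rose (7 adjusted over the list alone, list adjusted p = 0.00168, adjusted p = 0.129 with an estimated correlation). The regulator gene Gckr changed by 10.03 ± 0.14. Of the pericentral hepatocyte genes 13 of 20 rose and 3 fell (13 and 3 adjusted over the list alone, list adjusted p = 1.46e-06), with Cyp1a2 at least 1611-fold higher, and Glul, the glutamine synthetase gene of pericentral hepatocytes and kidney, at -0.07 ± 0.31 (adjusted p = 0.874). Of the periportal genes 13 of 18 rose and 2 fell (14 and 2 adjusted over the list alone, list adjusted p = 1.46e-07), with Cps1 at least 771-fold higher and Cyp2f2 up by 6.79 ± 0.37.

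Female-biased liver genes rose as a list, where 14 of 20 rose and 1 fell (15 and 1 adjusted over the list alone, list adjusted p = 1.46e-07). Cyp3a16 changed by 13.84 ± 0.51 and the sulfotransferase gene Sult3a1 by 13.65 ± 0.64. Of the male-biased genes 12 of 16 rose and 2 fell (12 and 2 adjusted over the list alone, list adjusted p = 8.90e-06, adjusted p = 0.0622 with an estimated correlation). Among major urinary protein genes, Mup20 changed by 12.20 ± 1.06 and Mup3 by 12.04 ± 1.04. Of the cholesterol synthesis genes 15 of 21 rose and 1 fell (15 and 1 adjusted over the list alone, list adjusted p = 3.11e-05, adjusted p = 0.401 with an estimated correlation), led by Sc5d (4.26 ± 0.36) and Insig1 (3.17 ± 0.58), and of the lipogenesis genes 12 of 18 rose and 1 fell (13 and 1 adjusted over the list alone, list adjusted p = 0.000214, adjusted p = 0.147 with an estimated correlation), led by Thrsp (5.20 ± 1.00) and Cidec (3.34 ± 1.21). Of the targets of the oxidative stress factor NRF2 10 of 19 rose and 2 fell (10 and 2 adjusted over the list alone, list adjusted p = 0.0293, adjusted p = 0.552 with an estimated correlation). Gstm3 changed by 3.88 ± 0.84 and Ces2g by 3.66 ± 0.18. The NRF2 call was lost without neo-liver array 3 or with normexp background correction. Cidec was not called without host kidney array 1 or 4 or neo-liver array 3 or 4 or in the fit of the 2 groups alone. Besides Saa2, Apoa1, Cyp3a16, Sult3a1 and Hamp, the genes furthest up included Cyp2a12 (13.85 ± 0.49), Cyp3a41b (13.71 ± 0.50) and Ces1c (13.69 ± 0.57). These genes, Cyp2c39, Slco1b2, Foxa2, Mup20 and Mup3, Saa2 excepted, were above background on 1 of 4 kidney arrays, and Cyp2c50 on 2. Their sizes thus lean on kidney signals below background.

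Of the Kupffer cell genes 15 of 18 rose (15 adjusted over the list alone, list adjusted p = 1.51e-10, adjusted p = 0.0730 with an estimated correlation). Vsig4, a complement receptor gene, changed by 8.95 ± 0.29. Of the stellate cell genes 19 of 24 rose and 2 fell (19 and 2 adjusted over the list alone, list adjusted p = 1.24e-09), led by the ligand gene Gdf2, at least 155-fold higher, and the lectin gene Colec10, at least 145-fold. Of the sinusoidal endothelial genes 16 of 21 rose and 4 fell (16 and 4 adjusted over the list alone, list adjusted p = 1.46e-07, adjusted p = 0.0849 with an estimated correlation), including Clec4g at 8.10 ± 0.22, and Oit3 (8.04 ± 0.26) and the hyaluronan receptor gene Lyve1 (5.78 ± 0.43), both above background on 1 of 4 kidney arrays. Genes shared by most endothelia moved both ways: 4 of 19 were higher and 8 lower (4 and 8 adjusted over the list alone, list adjusted p = 0.481), and Pecam1 differed by -0.10 ± 0.13 (adjusted p = 0.530). Of the matrix and myofibroblast genes 14 of 26 rose (14 adjusted over the list alone, list adjusted p = 0.000375, adjusted p = 0.333 with an estimated correlation), among them Fn1, for fibronectin, at 5.07 ± 0.24, Lum at 3.68 ± 0.30 and Col1a1, a chain of fibrillar collagen, at 2.13 ± 0.41. Of the lymphocyte genes 14 of 20 rose (15 adjusted over the list alone, list adjusted p = 0.000126, adjusted p = 0.218 with an estimated correlation). The B cell gene Ms4a1 changed by 2.39 ± 0.25 and the T cell gene Cd3d by 1.79 ± 0.36. Of the myeloid inflammation genes 13 of 20 rose and 1 fell (14 and 1 adjusted over the list alone, list adjusted p = 0.000642, adjusted p = 0.227 with an estimated correlation). The chemokine gene Cxcl9 changed by 4.86 ± 0.55 and Gpnmb, on 3 of 4 kidney arrays, by 4.80 ± 0.96. Of the interferon response genes 10 of 21 rose and 1 fell (10 and 1 adjusted over the list alone, list adjusted p = 0.00257, adjusted p = 0.429 with an estimated correlation). Bst2 changed by 3.24 ± 0.17 and Oasl1 by 3.02 ± 0.43. Of the proliferation genes 12 of 22 rose and 1 fell (14 and 1 adjusted over the list alone, list adjusted p = 0.00665, adjusted p = 0.600 with an estimated correlation). Bub1b changed by 2.78 ± 0.81 and Top2a by 2.75 ± 0.67, each above background on 2 of 4 kidney arrays. Mki67, a marker of cycling cells, changed by 1.60 ± 0.45. Bile duct genes were lower as a list, where 11 of 18 fell and 3 rose (12 and 3 adjusted over the list alone, list adjusted p = 0.0169, adjusted p = 0.147 with an estimated correlation): Epcam fell by 3.05 ± 0.23 and Cd24a fell by 2.65 ± 0.22, while the duct keratin gene Krt19 differed by 0.00 ± 0.31 (adjusted p = 0.996).

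Of the proximal tubule genes 17 of 24 fell (21 adjusted over the list alone, list adjusted p = 1.14e-06, adjusted p = 0.183 with an estimated correlation). Aadat, above background on 2 of 4 neo-liver arrays, changed by -5.49 ± 0.46 and Slc22a19 by -5.45 ± 0.45. Of the genes of the loop, distal tubule and collecting duct 27 of 29 fell (27 and 1 adjusted over the list alone, list adjusted p = 2.52e-08, adjusted p = 0.151 with an estimated correlation). Slc12a1, the sodium cotransporter gene of the thick ascending limb, changed by -4.78 ± 0.37 and the water channel gene Aqp4 by -3.68 ± 0.49. Of the podocyte genes 10 of 14 fell and 2 rose (10 and 2 adjusted over the list alone, list adjusted p = 0.0240, adjusted p = 0.147 with an estimated correlation). Npnt changed by -2.27 ± 0.29 and Tdrd5 by -1.78 ± 0.24. Of the developmental transcription factors of the kidney 19 of 21 fell and 1 rose (19 and 1 adjusted over the list alone, list adjusted p = 1.15e-08, adjusted p = 0.151 with an estimated correlation). Irx2, on 3 of 4 neo-liver arrays, changed by -4.38 ± 0.33 and Irx1 by -3.80 ± 0.35. The genes furthest down were Bcat1 (-6.47 ± 0.37), Slc7a12 (-6.07 ± 0.40), Serpina1f (-5.70 ± 0.36), the protease gene Mep1b (-5.70 ± 0.46), Tmem207 (-5.57 ± 0.40) and Pjvk (-5.55 ± 0.37), with Rhox6 at least 18.6-fold and Myh1 at least 14.5-fold lower. Of these, Bcat1, Tmem207 and Pjvk were above background on 2 of 4 neo-liver arrays. Cdkn1a, for the cell cycle inhibitor p21, differed by 1.43 ± 0.71 (adjusted p = 0.107). The fetal liver protein gene Afp rose by 1.34 ± 0.47 (adjusted p = 0.0281), a call lost without host kidney array 3 or neo-liver array 1 or 4. Lists not called, with their genes higher and lower and the same counts adjusted over the list alone, were PPARA targets (6 and 1 of 21, 6 and 1), adipocyte (3 and 1 of 9, 3 and 1) and adrenal cortex (3 and 0 of 6, 3 and 0). Others were circadian clock (0 and 2 of 20, 0 and 1), erythroid (0 and 2 of 8, 0 and 1) and fetal liver (5 and 6 of 15, 5 and 8). Others were immediate early (2 and 2 of 17, 2 and 2), muscle (2 and 2 of 5, 2 and 2) and p53 targets (7 and 6 of 23, 7 and 6). Their list adjusted p lay from 0.164 to 0.887. Median, mean and test direction differed in sign for fetal liver (-0.87, 0.18 and down). The 4 host kidney arrays lay on a slide of their own, so slide and group cannot be told apart in this comparison.

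Kidney RNA in neo-liver was estimated from 58 markers of 3 kidney epithelia at least 8-fold higher in host kidney than in control liver. The neo-liver arrays held 19.2%, 44.7%, 20.8% and 32.5% of the mean host kidney signal, a mean of 29.3% ± 11.9 (SD, n = 4), against 0.00900% to 0.0315% on the 4 host liver arrays (exact permutation test within mice, two-sided, p = 0.125, the smallest that 16 sign changes of 4 pairs allow). If these shares stand for kidney RNA, RNA of all other cells in neo-liver was diluted by -0.52 on the log2 scale on average and by -0.85 on array 2. The share depends on the markers: 10 markers of kidney cortex, listed after the pattern was seen, gave a mean of 45.9% and 7 of the outer stripe and medulla 12.2%. With the cortex medians the dilution would be -2.20 on array 2. Results after subtraction use the 58 markers. Of 838 genes enriched in host liver over host kidney, 830 were higher in neo-liver than in kidney and 480 lower than in host liver, with a median of -0.97 against host liver. Of 1057 kidney-enriched genes, 974 were higher in neo-liver than in host liver and 960 lower than in host kidney. Host liver itself had 6191 genes higher and 4870 lower than host kidney.

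**Figure D1:**
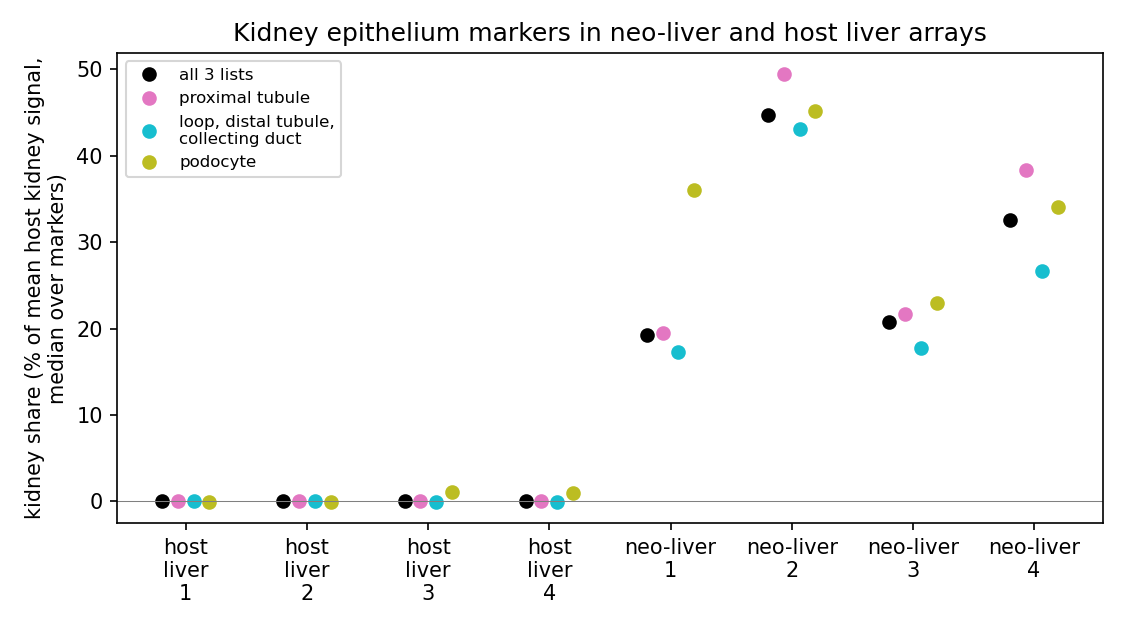
Kidney share of each host liver and neo-liver array, in % of the mean host kidney signal (y axis), as the median over all kidney markers (black) and over the markers of each epithelium (colours). Neo-liver arrays lie between 19.2% and 44.7% over all markers, and host liver arrays lie at or below 0.0315%.

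Neo-liver against control liver asked how far the ectopic tissue differed from liver of normal mice, with age, host injury, donor cells and site differing together. Cyp2f2, a periportal hepatocyte gene, fell by 4.24 ± 0.40 (18.9-fold, adjusted p = 2.24e-06, 4 against 3 arrays), Sds, a serine dehydratase gene, fell by 4.80 ± 0.59, and Etnppl, for a phospholyase of ethanolamine metabolism, fell by 5.27 ± 0.51. Col1a1 rose by 3.47 ± 0.45, Umod was at least 997-fold higher and Slc34a1 rose by 7.43 ± 0.38. In all, 3184 genes were higher and 4651 lower in neo-liver, of which 2273 and 1288 differed at least 2-fold.

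Of the periportal genes 14 of 18 fell and 1 rose (15 and 1 adjusted over the list alone, list adjusted p = 0.000137, adjusted p = 0.176 with an estimated correlation), a median of -2.42. Of the urea cycle and amino acid genes 18 of 18 fell (18 adjusted over the list alone, list adjusted p = 2.72e-07, adjusted p = 0.243 with an estimated correlation), a median of -2.57, with the glutaminase gene Gls2 at -4.05 ± 0.64. After subtraction of the kidney share from the neo-liver arrays these medians were -1.96 and -2.16. Both lists hold Hal, Sds, Gls2, Ass1, Cps1 and Arg1, so their falls are not independent. For pericentral genes 2 of 20 were higher and 7 lower (2 and 7 adjusted over the list alone, list adjusted p = 0.418), a median of -0.41, and Glul differed by -0.23 ± 0.33 (adjusted p = 0.593). For plasma protein genes 1 of 27 were higher and 10 lower (0 and 5 adjusted over the list alone, list adjusted p = 0.0802), a median of -0.50, while Alb fell by 0.60 ± 0.22 (adjusted p = 0.0387). Of the liver transcription factors 9 of 16 fell (10 adjusted over the list alone, list adjusted p = 0.00882, adjusted p = 0.0930 with an estimated correlation). Onecut1 changed by -2.58 ± 0.48, Cebpa by -1.81 ± 0.29 and Hnf4a by -0.62 ± 0.13. The transcription factor list call was lost after subtraction of the kidney share. Of the P450 genes 9 of 20 fell (9 adjusted over the list alone, list adjusted p = 0.0173, adjusted p = 0.542 with an estimated correlation). Cyp2b13 changed by -2.55 ± 0.76. Alb was not called without control liver array 1, 2 or 3 or neo-liver array 2, 3 or 4 or without a filter on dim probes. With quantile normalization the P450 list, Alb and Hnf4a were not called. After subtraction of the kidney share the P450 list, Alb and Cyp2b13 were not called. Neo-liver Alb was highest on array 1, with the lowest 75th percentile, so scaling may cause its differences between livers.

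Of the gluconeogenesis genes 8 of 11 fell (8 adjusted over the list alone, list adjusted p = 0.00114, adjusted p = 0.176 with an estimated correlation). The glucose transporter gene Slc2a2 changed by -1.62 ± 0.26. Of the cholesterol synthesis genes 16 of 21 fell (17 adjusted over the list alone, list adjusted p = 0.00114, adjusted p = 0.560 with an estimated correlation). Of the lipogenesis genes 14 of 18 fell (15 adjusted over the list alone, list adjusted p = 0.00183, adjusted p = 0.277 with an estimated correlation). Thrsp changed by -4.17 ± 1.08 and the fatty acid synthase gene Fasn by -3.27 ± 0.77. The lipogenesis list call was lost after subtraction of the kidney share. For bile acid genes 1 of 20 were higher and 10 lower (1 and 10 adjusted over the list alone, list adjusted p = 0.111). Cyp7a1 changed by -2.60 ± 0.68. The genes furthest down besides Etnppl and Sds were Pax2 (-7.03 ± 0.94), the methyltransferase gene Nnmt (-6.35 ± 1.03), Tiam2 (-4.84 ± 0.98), the clock-associated gene Ciart (-4.54 ± 1.07), Mup6 (-4.54 ± 0.80) and Mmd2 (-4.53 ± 0.60).

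Of the matrix and myofibroblast genes 19 of 26 rose (20 and 1 adjusted over the list alone, list adjusted p = 3.07e-07, adjusted p = 0.243 with an estimated correlation), a median of 1.61 and 1.61 after subtraction of the kidney share. Timp1, for an inhibitor of matrix proteases, was at least 18.0-fold higher, and Loxl1, above background on 2 of 3 control arrays, rose by 3.87 ± 0.54. For stellate cell genes 10 of 24 were higher and 5 lower (12 and 5 adjusted over the list alone, list adjusted p = 0.0643), and Lrat differed by -0.32 ± 0.25 (adjusted p = 0.320). For sinusoidal endothelial genes 3 of 21 were higher and 8 lower (3 and 8 adjusted over the list alone, list adjusted p = 0.306): Stab2 fell by 1.25 ± 0.22 and Lyve1 rose by 1.98 ± 0.47. For Kupffer cell genes 0 of 18 were higher and 2 lower (0 and 2 adjusted over the list alone, list adjusted p = 0.306), and Clec4f differed by -0.70 ± 0.50 (adjusted p = 0.259). Of the general endothelial genes 5 of 19 rose and 1 fell (4 and 1 adjusted over the list alone, list adjusted p = 0.0209, adjusted p = 0.478 with an estimated correlation), with Emcn at 2.11 ± 0.19, Cd34 at 2.10 ± 0.19 and Pecam1 at 0.10 ± 0.14 (adjusted p = 0.573). The general endothelial list call was lost without neo-liver array 1 or after subtraction of the kidney share. Of the bile duct genes 9 of 18 rose and 4 fell (9 and 4 adjusted over the list alone, list adjusted p = 0.0124, adjusted p = 0.176 with an estimated correlation), with Krt7 at least 23.3-fold and Epcam at least 8.26-fold higher and Krt19 at 0.03 ± 0.33 (adjusted p = 0.940). The bile duct call was lost with quantile normalization, and was lost with a turn in direction after subtraction of the kidney share. Krt7, Epcam and Emcn were not called and turned direction after subtraction of the kidney share. Of the fetal liver genes 11 of 15 rose (12 adjusted over the list alone, list adjusted p = 8.56e-06, adjusted p = 0.165 with an estimated correlation), including Tff3, at least 45.8-fold higher, and Ly6d at 5.74 ± 0.77, while Afp differed by 1.05 ± 0.51 (adjusted p = 0.103).

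Of the p53 targets 14 of 23 rose and 2 fell (14 and 3 adjusted over the list alone, list adjusted p = 0.00114, adjusted p = 0.243 with an estimated correlation), led by the stress cytokine gene Gdf15 (4.32 ± 0.37) and Phlda3 (3.18 ± 0.38). Of the proliferation genes 13 of 22 rose (15 adjusted over the list alone, list adjusted p = 0.000137, adjusted p = 0.504 with an estimated correlation). The cyclin gene Ccnb1 was at least 8.97-fold and Tpx2 at least 5.21-fold higher, and Mki67 changed by 2.16 ± 0.49. The probes of Tpx2 disagreed. Of the immediate early genes 10 of 17 rose (11 adjusted over the list alone, list adjusted p = 0.000334, adjusted p = 0.451 with an estimated correlation). Egr1 changed by 4.56 ± 0.65 and Fos by 4.50 ± 0.93. Of the myeloid inflammation genes 13 of 20 rose (13 adjusted over the list alone, list adjusted p = 2.97e-05, adjusted p = 0.243 with an estimated correlation), with the calprotectin subunit genes S100a8 (5.03 ± 1.12) and S100a9 (4.55 ± 1.08). Of the lymphocyte genes 7 of 20 rose and 3 fell (7 and 3 adjusted over the list alone, list adjusted p = 0.0380, adjusted p = 0.560 with an estimated correlation), with the plasma cell genes Jchain (4.04 ± 0.59) and Mzb1 (2.13 ± 0.48). The lymphocyte list call was lost without control liver array 1 or neo-liver array 1 or with quantile normalization. Cdkn1a rose by 2.34 ± 0.77 (adjusted p = 0.0215). Cdkn1a was not called without control liver array 1 or 2 or neo-liver array 4. Ccnb1 was not called without control liver array 3 or with normexp background correction. Tpx2 was not called with normexp background correction. Jchain, Mzb1 and Fos were not called after subtraction of the kidney share.

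Of the proximal tubule genes 21 of 24 rose and 1 fell (21 and 1 adjusted over the list alone, list adjusted p = 9.00e-19, adjusted p = 0.0926 with an estimated correlation). Of the distal genes 27 of 29 rose (27 and 1 adjusted over the list alone, list adjusted p = 1.33e-20, adjusted p = 0.0926 with an estimated correlation). Of the podocyte genes 11 of 14 rose and 1 fell (11 and 1 adjusted over the list alone, list adjusted p = 3.95e-06). Of the kidney transcription factors 17 of 21 rose and 1 fell (17 and 1 adjusted over the list alone, list adjusted p = 7.31e-14, adjusted p = 0.165 with an estimated correlation). No control array had signal above background for Cltrn, Lrp2, Cdh16, Hsd3b4, Dao, Kap or Mep1a, which were between at least 530-fold (Kap) and at least 2439-fold (Cltrn) higher and, with Umod, the genes furthest up. Hoxd8 was at least 44.0-fold and Tfap2b at least 20.1-fold higher, and the podocyte factor gene Wt1, on 1 of 3 control arrays, rose by 5.28 ± 0.61. Umod was not called after subtraction of the kidney share. Lists not called, with the same pairs of counts, were NRF2 targets (3 and 1 of 19, 1 and 1), PPARA targets (2 and 5 of 21, 1 and 3), acute phase response (1 and 2 of 19, 0 and 0) and adipocyte (3 and 0 of 9, 2 and 0). Others were adrenal cortex (1 and 3 of 6, 1 and 3), circadian clock (0 and 5 of 20, 0 and 4), erythroid (1 and 0 of 8, 1 and 0) and female-biased liver (2 and 8 of 20, 2 and 9). Others were interferon response (8 and 2 of 21, 8 and 2), male-biased liver (2 and 7 of 16, 2 and 8) and muscle (3 and 1 of 5, 3 and 1). Their list adjusted p lay from 0.0549 to 0.734. Median, mean and test direction differed in sign for acute phase response (0.37, -0.03 and up) and adrenal cortex (-0.26, 0.24 and down).

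Neo-liver and control liver lay on one slide, where a fit of these 7 arrays alone gave 3165 genes higher and 4459 lower. That fit kept the periportal (list adjusted p = 0.000123), matrix (2.46e-08) and immediate early (2.28e-05) calls, with adjusted p = 0.248, 0.286 and 0.399 with an estimated correlation. It also called 6 lists that the fit of all arrays did not: plasma proteins (-0.50), female-biased (-1.31) and erythroid genes (1.32), each at list adjusted p = 0.0220, stellate cell genes (0.65, list adjusted p = 0.0271), and interferon response (0.56) and circadian genes (-0.87), each at list adjusted p = 0.0325. With an estimated correlation their adjusted p lay from 0.248 to 0.692. The median of all genes was -0.15, and quantile normalization moved it to -0.02 and the share of higher genes among those called from 40.6% to 52.2%. Without genes at least 2-fold higher in host kidney than in host liver, 1240 genes were higher.

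**Figure D2:**
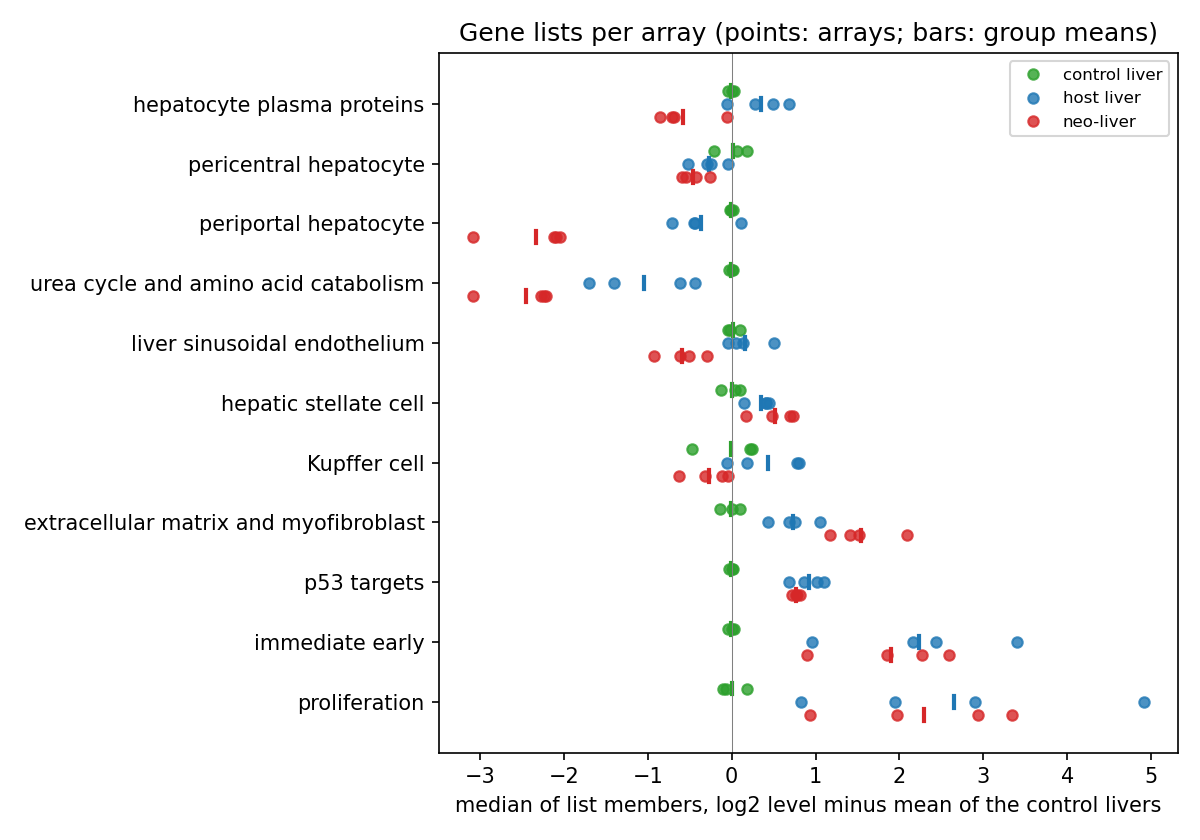
Median log2 level of the members of 11 gene lists on each liver array relative to the mean of the control livers (x axis), where points are arrays and bars are group means. Periportal medians of the 4 neo-liver arrays lie between -3.09 and -2.05, those of the host livers between -0.71 and 0.11.

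Neo-liver against host liver set the ectopic tissue beside the injured liver of hosts of the same age range. Hsd17b6, a steroid dehydrogenase gene, fell by 3.67 ± 0.53, Sds fell by 3.65 ± 0.55 and Cyp2f2 fell by 3.46 ± 0.37 (adjusted p = 9.19e-06, 4 against 4 arrays). Col1a1 rose by 2.36 ± 0.41. Slc34a1 rose by 7.75 ± 0.35 and Umod, above background on 2 of 4 host liver arrays, by 9.79 ± 0.48. In all, 2670 genes were higher and 4921 lower, of which 1714 and 637 differed at least 2-fold.

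Of the periportal genes 14 of 18 fell and 1 rose (16 and 1 adjusted over the list alone, list adjusted p = 0.000434, adjusted p = 0.250 with an estimated correlation), a median of -1.63 that was -1.29 after subtraction of the kidney share. Of the urea cycle and amino acid genes 14 of 18 fell (16 adjusted over the list alone, list adjusted p = 0.000538, adjusted p = 0.714 with an estimated correlation), a median of -1.44 and -0.98 after subtraction, with Hal, for histidine lyase, at -2.83 ± 0.29. For pericentral genes 3 of 20 were higher and 4 lower (3 and 4 adjusted over the list alone, list adjusted p = 0.826), and Glul differed by 0.08 ± 0.31 (adjusted p = 0.838). Of the plasma protein genes 18 of 27 fell (19 adjusted over the list alone, list adjusted p = 0.000593, adjusted p = 0.722 with an estimated correlation). The fibrinogen gene Fga changed by -1.25 ± 0.31, the plasminogen gene Plg by -1.18 ± 0.45 and Alb by -0.79 ± 0.21. The plasma protein list call was lost with quantile normalization or after subtraction of the kidney share. Of the acute phase genes 11 of 19 fell (11 adjusted over the list alone, list adjusted p = 0.0349, adjusted p = 0.722 with an estimated correlation). Orm3 changed by -2.86 ± 0.76 and Saa4 by -2.00 ± 0.50. The acute phase list call was lost without host liver array 1 or neo-liver array 2, with quantile normalization, with median centring or after subtraction of the kidney share. Of the liver transcription factors 11 of 16 fell (12 adjusted over the list alone, list adjusted p = 0.00946, adjusted p = 0.0776 with an estimated correlation). Nr0b2 changed by -1.58 ± 0.58, Onecut1 by -1.37 ± 0.44 and Hnf4a by -0.56 ± 0.12. The transcription factor list call was lost after subtraction of the kidney share. Of the P450 genes 7 of 20 fell (7 adjusted over the list alone, list adjusted p = 0.0219, adjusted p = 0.722 with an estimated correlation). Cyp2c37 changed by -1.55 ± 0.47. The P450 list call was lost without host liver array 2 or neo-liver array 1, with normexp background correction, with quantile normalization, with median centring or after subtraction of the kidney share. Cyp7a1 differed by 0.23 ± 0.63 (adjusted p = 0.783).

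Plg was not called without host liver array 1, 2, 3 or 4 or neo-liver array 2, 3 or 4, with quantile normalization, with array weights, with slide as a random block or after subtraction of the kidney share. Nr0b2 was not called without host liver array 2 or 3 or neo-liver array 1, with quantile normalization, in the fit of the 2 groups alone, with slide as a random block or after subtraction of the kidney share. Onecut1 was not called without host liver array 1 or 4 or neo-liver array 2, in the fit of the 2 groups alone or after subtraction of the kidney share. Hnf4a was not called and turned direction with quantile normalization. Cyp2c37 was not called with quantile normalization, with the mean of all its probes, in the fit of the 2 groups alone or after subtraction of the kidney share. The genes furthest down besides Hsd17b6, Sds and Cyp2f2 were Mmd2 (-4.31 ± 0.55), the sulfotransferase gene Sult5a1 (-3.96 ± 0.27), Mup5 (-3.87 ± 0.70), Etnppl (-3.01 ± 0.47) and Lipn (-3.15 ± 0.68), the last above background on 1 of 4 neo-liver and 3 of 4 host liver arrays.

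Of the matrix genes 17 of 26 rose and 1 fell (17 and 1 adjusted over the list alone, list adjusted p = 9.49e-05, adjusted p = 0.559 with an estimated correlation), a median of 0.95 and 0.85 after subtraction of the kidney share, with Loxl1, on 3 of 4 host liver arrays, at 2.84 ± 0.50. Of the fetal liver genes 6 of 15 rose (6 adjusted over the list alone, list adjusted p = 0.000908, adjusted p = 0.312 with an estimated correlation), with Gpc3, a glypican gene, at 4.39 ± 0.25 and Tff3 at 3.54 ± 1.29, both on 3 of 4 host liver arrays, while Afp, on 3 of 4 as well, differed by 0.88 ± 0.47 (adjusted p = 0.140). The fetal list call was lost after subtraction of the kidney share. For sinusoidal endothelial genes 3 of 21 were higher and 10 lower (3 and 11 adjusted over the list alone, list adjusted p = 0.168), where Stab2 fell by 1.53 ± 0.20 and Lyve1 rose by 1.56 ± 0.43. For stellate cell genes 6 of 24 were higher and 7 lower (6 and 7 adjusted over the list alone, list adjusted p = 0.409), and Lrat differed by 0.14 ± 0.23 (adjusted p = 0.646). Of the Kupffer cell genes 7 of 18 fell (7 adjusted over the list alone, list adjusted p = 0.0390, adjusted p = 0.754 with an estimated correlation), with Folr2 at -0.93 ± 0.29, and Clec4f differed by -1.07 ± 0.46 (adjusted p = 0.0689). Cd163 was below background in both groups. The Kupffer call was lost without host liver array 1 or 4 or neo-liver array 2 or 3, with normexp background correction, with quantile normalization or with median centring, and was lost with a turn in direction after subtraction of the kidney share. Of the myeloid inflammation genes 4 of 20 rose (4 adjusted over the list alone, list adjusted p = 0.0349, adjusted p = 0.722 with an estimated correlation). Spp1, for osteopontin, changed by 3.34 ± 0.27 and the receptor gene Trem2 by 1.70 ± 0.44. The myeloid inflammation list call was lost without host liver array 2 or neo-liver array 1 or 4 or with quantile normalization. Of the bile duct genes 8 of 18 rose and 3 fell (8 and 3 adjusted over the list alone, list adjusted p = 0.00259, adjusted p = 0.105 with an estimated correlation), with Krt7, on 1 of 4 host liver arrays, at 4.14 ± 0.29 and Krt19 at -0.60 ± 0.31 (adjusted p = 0.124). The bile duct call was lost and turned direction after subtraction of the kidney share. Tff3 was not called without host liver array 3 or 4 or neo-liver array 1 or 3, with quantile normalization or in the fit of the 2 groups alone. Folr2 was not called without host liver array 1 or 4 or neo-liver array 3, with quantile normalization, in the fit of the 2 groups alone or with array weights. Spp1 and Krt7 were not called and turned direction after subtraction of the kidney share. Pecam1 differed by -0.27 ± 0.13 (adjusted p = 0.0846), Mki67 by -0.21 ± 0.45 (adjusted p = 0.727) and Cdkn1a, whose probes disagreed, by -0.69 ± 0.71 (adjusted p = 0.443).

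Of the proximal tubule genes 21 of 24 rose (21 adjusted over the list alone, list adjusted p = 4.23e-23). Of the distal genes 27 of 29 rose (27 adjusted over the list alone, list adjusted p = 2.64e-27). Of the podocyte genes 11 of 14 rose and 1 fell (11 and 1 adjusted over the list alone, list adjusted p = 4.16e-07). Of the kidney transcription factors 20 of 21 rose and 1 fell (20 and 1 adjusted over the list alone, list adjusted p = 1.33e-19, adjusted p = 0.0808 with an estimated correlation). The genes furthest up besides Umod were Dao (at least 485-fold), Cubn (at least 389-fold), Car12 (at least 296-fold), Slc7a9 (at least 244-fold), Cdh16 (10.05 ± 0.46), Cltrn (10.03 ± 0.65) and Lrp2 (9.72 ± 0.58). Cdh16 and Lrp2 were above background on 2 and Cltrn on 3 of 4 host liver arrays. Hoxd8 was at least 33.2-fold and Tfap2b at least 15.2-fold higher, and Clic5, on 3 of 4 host liver arrays, rose by 4.67 ± 0.27. Umod and Lrp2 were not called and turned direction after subtraction of the kidney share. Clic5 was not called after subtraction of the kidney share. Lists not called, with the same pairs of counts, were NRF2 targets (0 and 5 of 19, 0 and 5), PPARA targets (0 and 6 of 21, 0 and 5), adipocyte (3 and 0 of 9, 3 and 0) and adrenal cortex (0 and 1 of 6, 0 and 1). Others were bile acid synthesis and transport (2 and 9 of 20, 2 and 11), cholesterol synthesis (0 and 3 of 21, 0 and 3), circadian clock (0 and 1 of 20, 0 and 1) and erythroid (1 and 0 of 8, 1 and 0). Others were female-biased liver (3 and 7 of 20, 3 and 7), gluconeogenesis (0 and 5 of 11, 0 and 6), immediate early (1 and 2 of 17, 1 and 1) and interferon response (1 and 6 of 21, 1 and 5). Others were lipogenesis (0 and 5 of 18, 0 and 5), lymphocyte (2 and 2 of 20, 1 and 2), male-biased liver (3 and 8 of 16, 3 and 9) and muscle (1 and 1 of 5, 1 and 1). Others were p53 targets (4 and 6 of 23, 4 and 6), pan-endothelium (3 and 1 of 19, 3 and 1) and proliferation (1 and 0 of 22, 0 and 0). Their list adjusted p lay from 0.0505 to 0.981. The gluconeogenesis list was called with the replicate block (-0.61, list adjusted p = 0.0487, adjusted p = 0.517 with an estimated correlation) and not with mouse as a random block (list adjusted p = 0.0505). Median, mean and test direction differed in sign for circadian clock (-0.26, -0.25 and up), hepatic stellate cell (-0.02, 0.13 and up), immediate early (-0.51, -0.29 and up), p53 targets (-0.06, -0.12 and up), pan-endothelium (-0.11, 0.14 and up), pericentral hepatocyte (-0.19, -0.07 and up) and proliferation (-0.21, -0.21 and up).

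Without genes at least 2-fold higher in host kidney than in host liver, 478 genes were higher in neo-liver than in host liver. The median of all genes was -0.21, and it was -0.07 with quantile normalization and -0.41 with median centring. The share of higher genes among those called was 35.2%, against 24.7% with normexp background correction, 50.9% with quantile normalization and 23.1% with median centring. No slide held arrays of both groups, so slide and group cannot be told apart in this comparison. With slide as a random block, which does not part them, 2535 and 4577 genes were called.

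**Figure D3:**
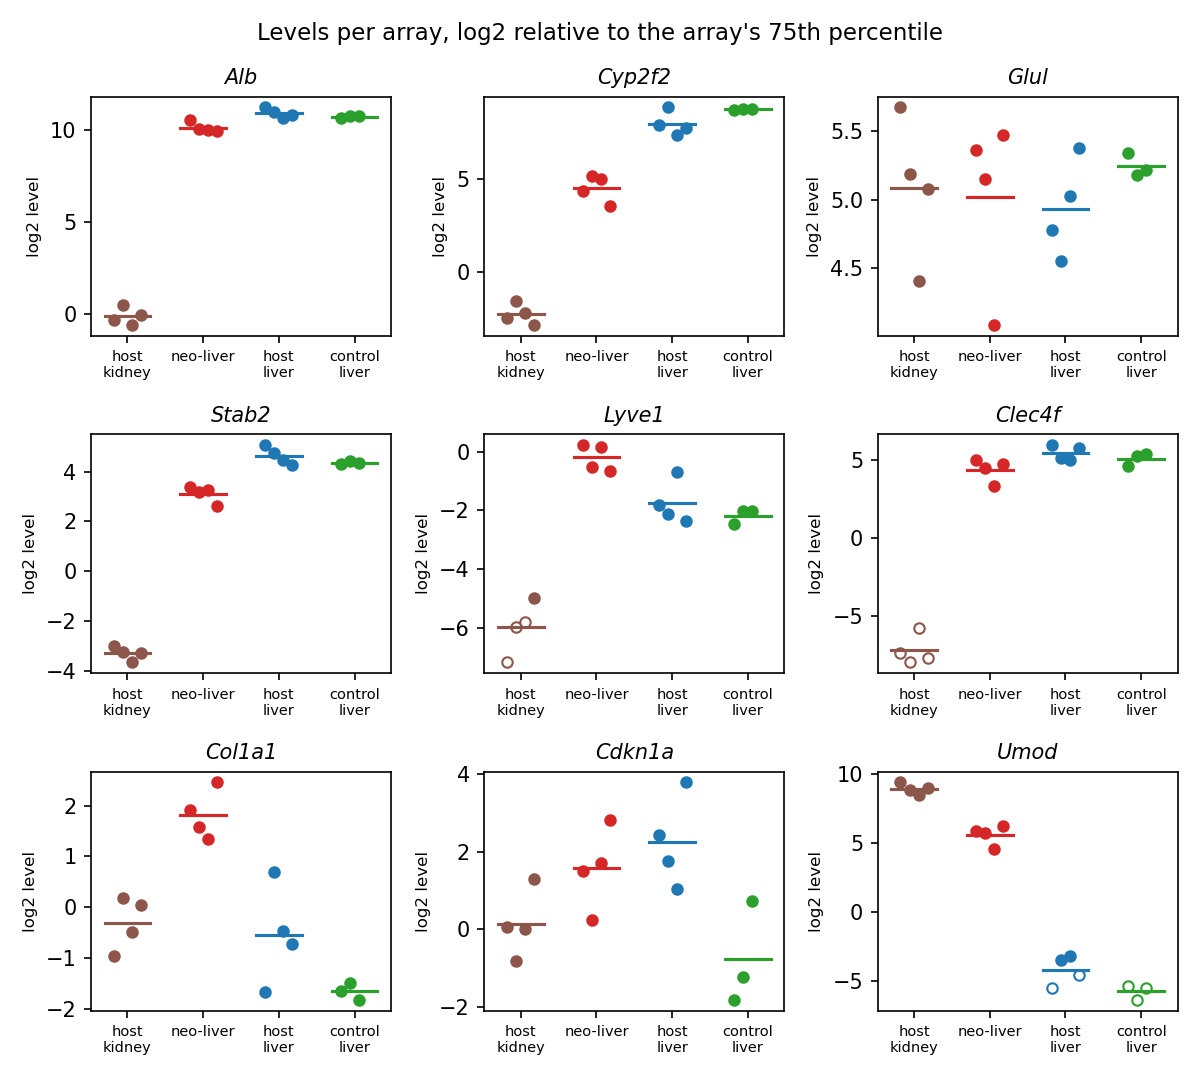
Log2 level of 9 lead genes on each array relative to the array's 75th percentile (y axes), by group (x axes), where filled points are above background, open points are not, and bars are group means. Cyp2f2 and Stab2 are lower in neo-liver than on each liver array of the hosts and controls, Col1a1 is higher in neo-liver than on any other array, and Glul overlaps between groups.

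Host liver against control liver asked what injured liver showed long after monocrotaline, with age differing together with injury and transplantation. Fos rose by 5.86 ± 0.93 and Egr1 by 5.35 ± 0.65, both for transcription factors induced within minutes of stress, and Gdf15 rose by 5.06 ± 0.37 (33.3-fold, adjusted p = 4.90e-06, 4 against 3 arrays). Cdkn2a, which encodes the senescence-linked inhibitor p16, was at least 15.8-fold higher and the mitotic kinase gene Nek2 at least 8.92-fold. Host liver had 2099 genes higher and 1755 lower than control liver, of which 721 and 644 differed at least 2-fold.

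Of the p53 targets 13 of 23 rose and 1 fell (15 and 1 adjusted over the list alone, list adjusted p = 1.58e-05, adjusted p = 0.521 with an estimated correlation). Btg2 changed by 3.19 ± 0.72. Of the immediate early genes 10 of 17 rose (12 adjusted over the list alone, list adjusted p = 1.58e-05, adjusted p = 0.521 with an estimated correlation). Of the proliferation genes 14 of 22 rose (19 and 1 adjusted over the list alone, list adjusted p = 2.02e-05, adjusted p = 0.589 with an estimated correlation). Ccnb1 was at least 10.6-fold and Tpx2 at least 6.02-fold higher, each above background on 3 of 4 host liver and no control arrays. Mki67 changed by 2.37 ± 0.49. Of the fetal liver genes 5 of 15 rose (5 adjusted over the list alone, list adjusted p = 0.00639, adjusted p = 0.521 with an estimated correlation). Ly6d changed by 5.11 ± 0.77 and the imprinted gene Peg3 by 2.19 ± 0.53. Of the erythroid genes 5 of 8 rose (7 adjusted over the list alone, list adjusted p = 0.00607, adjusted p = 0.589 with an estimated correlation). Of the globin genes, Hbb-b2 changed by 2.38 ± 0.70 and Hbb-bs by 2.26 ± 0.67. Cdkn1a rose by 3.03 ± 0.77 (adjusted p = 0.0126). Other genes furthest up were Ppp1r3g, on 2 of 3 control arrays, at 4.96 ± 0.60 and the pantetheinase gene Vnn1 at 4.78 ± 1.07. Cdkn1a was not called without control liver array 1 or 2. Ccnb1 was not called without control liver array 2 or 3 or host liver array 3, with normexp background correction or in the fit of the 2 groups alone. Hbb-b2 and Hbb-bs were not called without control liver array 1, 2 or 3 or host liver array 1 or 4.

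Of the urea cycle and amino acid genes 7 of 18 fell (8 adjusted over the list alone, list adjusted p = 1.58e-05, adjusted p = 0.521 with an estimated correlation). Asl, for a urea cycle enzyme, changed by -1.60 ± 0.33 and the methyltransferase gene Gnmt by -1.59 ± 0.51. Of the cholesterol synthesis genes 5 of 21 fell (6 adjusted over the list alone, list adjusted p = 0.000216, adjusted p = 0.589 with an estimated correlation). Lss changed by -1.35 ± 0.37. Of the lipogenesis genes 6 of 18 fell (7 adjusted over the list alone, list adjusted p = 0.00152, adjusted p = 0.521 with an estimated correlation). Fasn changed by -2.74 ± 0.77 and Elovl6 by -1.78 ± 0.61. Of the gluconeogenesis genes 4 of 11 fell (6 adjusted over the list alone, list adjusted p = 0.00612, adjusted p = 0.521 with an estimated correlation). Slc2a2 changed by -1.08 ± 0.26. Of the circadian genes 3 of 20 fell (2 adjusted over the list alone, list adjusted p = 0.0164, adjusted p = 0.521 with an estimated correlation). Ciart, on 3 of 4 host liver arrays, changed by -4.23 ± 1.07 and Usp2 by -2.17 ± 0.41. Cyp7a1 fell by 2.83 ± 0.68. Gnmt was not called without control liver array 1, 2 or 3 or host liver array 1, 3 or 4 or in the fit of the 2 groups alone. Lss was not called without control liver array 1. Fasn was not called without control liver array 1 or 3 or host liver array 3 or 4. Elovl6 was not called without control liver array 1, 2 or 3 or host liver array 2, 3 or 4, with quantile normalization, without a filter on dim probes, with the mean of all its probes, in the fit of the 2 groups alone or with slide as a random block. The genes furthest down besides Ciart were the insulin-regulated glucose transporter gene Slc2a4 (-4.11 ± 0.51), Mup6 (-3.65 ± 0.80), Ell3 (-3.64 ± 0.88), Slc26a4 (-3.43 ± 0.69, on 3 of 4 host liver arrays) and Wscd1 (-3.25 ± 0.46, on 1 of 4), with Cox17 at least 3.96-fold and Klk11 at least 5.30-fold lower. For periportal genes 0 of 18 were higher and 3 lower (0 and 3 adjusted over the list alone, list adjusted p = 0.116), and Cyp2f2 differed by -0.78 ± 0.40 (adjusted p = 0.176). For pericentral genes 0 of 20 were higher and 4 lower (0 and 4 adjusted over the list alone, list adjusted p = 0.0951), and Glul differed by -0.31 ± 0.33 (adjusted p = 0.525). Both of these lists were called lower with normexp background correction (list adjusted p = 0.0284 and 0.0355) and with median centring (0.0380 and 0.0314), with adjusted p = 0.440 and 0.577 for both with an estimated correlation.

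Of the matrix genes 7 of 26 rose (9 adjusted over the list alone, list adjusted p = 0.00245, adjusted p = 0.589 with an estimated correlation), with Timp1 at least 5.46-fold higher, Col4a1, a basement membrane collagen gene, at 1.22 ± 0.31 and Col1a1 at 1.11 ± 0.45 (adjusted p = 0.0846). Of the myeloid inflammation genes 8 of 20 rose (9 adjusted over the list alone, list adjusted p = 0.00112, adjusted p = 0.521 with an estimated correlation). S100a8 changed by 3.58 ± 1.12 and S100a9 by 3.34 ± 1.08. Of the interferon response genes 9 of 21 rose (9 adjusted over the list alone, list adjusted p = 0.00125, adjusted p = 0.589 with an estimated correlation). Ifi44 changed by 2.25 ± 0.61 and Oas1a by 2.01 ± 0.47. Of the acute phase genes 7 of 19 rose (7 adjusted over the list alone, list adjusted p = 0.00250, adjusted p = 0.589 with an estimated correlation). The lipocalin gene Lcn2 changed by 2.74 ± 0.85 and the metallothionein gene Mt2 by 1.92 ± 0.59. Of the lymphocyte genes 5 of 20 rose (7 and 1 adjusted over the list alone, list adjusted p = 0.0255, adjusted p = 0.589 with an estimated correlation). Jchain changed by 2.30 ± 0.59 and Ms4a1 by 1.86 ± 0.27. The lymphocyte list call was lost without control liver array 1 or host liver array 1 or with normexp background correction. Of the general endothelial genes 5 of 19 rose and 1 fell (6 and 1 adjusted over the list alone, list adjusted p = 0.0427, adjusted p = 0.589 with an estimated correlation). Plvap changed by 0.84 ± 0.15 and Egfl7 by 0.83 ± 0.17. The general endothelial list call was lost without control liver array 3 or host liver array 1 or with quantile normalization. Timp1 was not called with normexp background correction. S100a8 was not called without control liver array 1, 2 or 3 or host liver array 1, 3 or 4. S100a9 was not called without control liver array 1, 2 or 3 or host liver array 1, 3 or 4, with quantile normalization, without a filter on dim probes or with slide as a random block. Ifi44 was not called without control liver array 1 or in the fit of the 2 groups alone. Lcn2 was not called without control liver array 1, 2 or 3 or host liver array 1 or 4 or in the fit of the 2 groups alone. Mt2 was not called without control liver array 1, 2 or 3 or host liver array 1, 3 or 4 or in the fit of the 2 groups alone. Jchain was not called without control liver array 1.

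For stellate cell genes 4 of 24 were higher and 0 lower (4 and 0 adjusted over the list alone, list adjusted p = 0.125). For Kupffer cell genes 0 of 18 were higher and 1 lower (0 and 0 adjusted over the list alone, list adjusted p = 0.306). For sinusoidal endothelial genes 0 of 21 were higher and 0 lower (0 and 0 adjusted over the list alone, list adjusted p = 0.434). By limma, 4 sinusoidal endothelial and 0 P450 genes had an unadjusted p under 0.05. Lead genes that did not pass were Alb at 0.19 ± 0.22 (adjusted p = 0.555), Hnf4a at -0.06 ± 0.13 (0.761), Stab2 at 0.28 ± 0.22 (0.363), Lyve1 at 0.42 ± 0.47 (0.542), Lrat at -0.45 ± 0.25 (0.209) and Clec4f at 0.38 ± 0.50 (0.610). So were Pecam1 at 0.37 ± 0.14 (0.0606), Krt19 at 0.64 ± 0.33 (0.182), Afp, on 3 of 4 host liver arrays, at 0.17 ± 0.51 (0.835) and Slc34a1, whose probes disagreed, at -0.32 ± 0.38 (0.563). Umod was above background on 2 of 4 host liver and no control arrays, at least 1.13-fold higher. Umod was not called without control liver array 1, 2 or 3 or host liver array 2, 3 or 4, with normexp background correction, with quantile normalization, without a filter on dim probes, in the fit of the 2 groups alone, with slide as a random block or with mouse as a random block. Lists not called, with the same pairs of counts, were NRF2 targets (1 and 0 of 19, 0 and 0), PPARA targets (1 and 0 of 21, 1 and 0), adipocyte (1 and 0 of 9, 1 and 0) and adrenal cortex (1 and 0 of 6, 1 and 1). Others were bile acid synthesis and transport (2 and 3 of 20, 2 and 3), cholangiocyte (2 and 3 of 18, 2 and 3), cytochrome P450 genes (0 and 0 of 20, 0 and 0) and female-biased liver (0 and 2 of 20, 0 and 1). Others were hepatocyte plasma proteins (3 and 0 of 27, 1 and 0), kidney developmental transcription factors (0 and 5 of 21, 0 and 5), kidney distal epithelium (3 and 2 of 29, 2 and 2) and kidney podocyte (1 and 2 of 14, 1 and 2). Others were kidney proximal tubule (3 and 1 of 24, 3 and 1), liver transcription factors (1 and 0 of 16, 0 and 0), male-biased liver (0 and 2 of 16, 0 and 1) and muscle (0 and 1 of 5, 0 and 1). Their list adjusted p lay from 0.0576 to 0.994. Median, mean and test direction differed in sign for adrenal cortex (0.06, 0.69 and down), cytochrome P450 drug metabolism (0.04, -0.01 and down), kidney developmental transcription factors (0.40, -0.06 and up), kidney distal epithelium (0.26, 0.04 and down), kidney podocyte (0.10, 0.12 and down), male-biased liver (-0.04, 0.01 and down) and muscle (0.09, -0.08 and down).

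The count of genes called between host liver and control liver rested on the number of controls: without control array 1, 2 or 3 it was 1206, 1210 or 1255 higher, and without control array 1 or 2 it was 1069 or 1092 lower. With only these 7 arrays in the fit, 1293 genes were higher. No slide held arrays of both groups, so slide and group cannot be told apart here either, and with slide as a random block, which does not part them, 1845 were higher and 1555 lower. The median of all genes was 0.08 and became 0.22 with median centring, which moved the share of higher genes among those called from 54.5% to 73.2%.

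Changes against control liver overlapped between neo-liver and host liver. Genes higher in both numbered 1158, against 428 for independent lists of these sizes, and genes lower in both 1179 against 523, while 149 were called in opposite directions. Simulated unchanged groups with the same 3 controls gave means of 0 higher and 0.01 lower, no baseline here, as hardly any gene was called. Without control array 1, 2 or 3 the overlap was 698, 743 or 736 higher and 659, 684 or 738 lower. Across genes, which are not independent replicates, the differences had r = 0.54 (0.57 simulated) and a covariance of 0.517 (0.0514 simulated). The 3 controls could not be split into parts of 2, so overlap due to shared controls was not measured, nor was overlap due to shared mice.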

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

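Of the tests in this part, those on other splits of the arrays were set before the data were examined, and those on the 3 patterns that follow were chosen after the result was seen.

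Periportal hepatocyte genes were lower in neo-liver than in control liver, with list medians per array from -3.09 to -2.05 (list adjusted p = 0.000137, or 0.176 with an estimated correlation). Fewer hepatocytes or dilution by RNA of other cells, kidney cortex included, would lower plasma protein genes alike, which hepatocytes also make and which host kidney held at list medians of -8.80 or lower. These had a median of -0.50 (list adjusted p = 0.0802, and within the slide 0.0220, or 0.692 with an estimated correlation). The contrast of periportal minus plasma protein medians was -1.76 ± 0.56 in neo-liver (SD, n = 4, exact permutation test against control liver, p = 0.0286 of 35 splits). Host liver showed part of it, at -1.12, -0.17, -0.39 and -1.20 on arrays 1 to 4 (exact permutation test, p = 0.0857), against -2.06, -1.24, -1.34 and -2.40 in neo-liver. Within mice neo-liver lay lower by -1.04 ± 0.12 (range -1.20 to -0.94, exact test within mice, p = 0.125, the smallest that 16 sign changes allow), which argues against dilution as the whole cause. With the cortex dilution added back, neo-liver periportal medians were -1.54, 0.11, -1.48 and -2.36 on arrays 1 to 4. Age as the whole cause is argued against by host liver of the same age range, where neo-liver periportal medians lay lower within each mouse, by -1.97 ± 0.38 (range -2.38 to -1.60, exact test within mice, p = 0.125). The tests within mice came after tests without pairs, and their 2 groups lay on different slides. How much dilution and age each add stays open. Zonation set by the ectopic site, donor cells or the hosts' injury may also contribute and was not tested.

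Kidney genes were present in neo-liver. Kidney tissue in the dissected samples, or kidney cells within the graft, may be the source, and the 99 of the 100 kidney-enriched genes brightest in host kidney that were called higher in neo-liver than in host liver restate the pattern and do not decide it. Markers of kidney cortex, next to the capsule, reached a mean share of 45.9% over 10 markers, against 12.2% over 7 markers of the outer stripe and medulla. All were measured on the same 4 arrays and many vary together, so no p over markers is given. The cortex share was higher on 4 of 4 arrays, at 33.0%, 78.2%, 32.4% and 39.6% against 6.17%, 19.1%, 6.39% and 10.9%. Whether this RNA came from cortex carried over by dissection or from kidney cells inside the graft stays open, and the 17 zone markers used, of 23 listed after the pattern was seen, include several that are also in the kidney lists behind the share.

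Of the immediate early genes 10 of 17 were higher in host liver than in control liver (list adjusted p = 1.58e-05, or 0.521 with an estimated correlation) and 10 of 17 in neo-liver (0.000334, or 0.451). Slide as the cause is argued against for neo-liver, since the rise had a median of 2.13 within the slide shared with the controls (list adjusted p = 2.28e-05, adjusted p = 0.399 with an estimated correlation). For host liver, slide and group cannot be told apart: its lowest array, at 0.96, lay on a slide without controls. State or handling of the whole animal may contribute, as number 2 was lowest in host kidney, host liver and neo-liver (0.77, 0.96 and 0.90), a chance of 0.0625. Age cannot be told apart from treatment either, as the youngest host was 28 weeks older than the controls.

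Of 35 splits, the real one called most genes for neo-liver against control liver (7835, highest other 4042). The same held for host liver against control liver (3854, highest other 2115). A share of 1 in 35, the smallest possible, argues against chance but does not exclude it. For neo-liver against host kidney (8230 genes) and against host liver (7591), the 8 splits that part every pair of one number cannot give a share under 0.05, 1 split was as large, and the highest other called 0 genes by limma in both. Over all 35 splits the highest other was 0 and 294.

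Some arrays lay far from the others of their group, in 23 of 521 groups of 4 tested (4.41%), where chance gives about 1 in 20. In host kidney these were, as list medians relative to control liver, female-biased genes on array 2 (-7.93, others -6.75 to -6.51), and stellate cell (-2.24, others -1.70 to -1.61) and pericentral genes (-3.11, others -2.25 to -2.12) on array 1. As log2 levels they were on array 2 Clec4g (-3.035, others -3.42 to -3.36), Cyp2c37 (-2.83, others -3.38 to -3.29), Egr1 (1.59, others 3.31 to 3.49) and Thrsp (1.84, others -1.24 to -0.84). Others were Hoxd8 on array 1 (3.29, others 2.89 to 2.92), and Afp (-4.46, others -3.44 to -3.24) and Tiam2 (-2.31, others -1.66 to -1.56) on array 3. In host liver they were the stellate cell median (0.15, others 0.40 to 0.45) and the Saa4 level (7.04, others 5.26 to 5.54) on array 1, and the Lum level on array 3 (1.24, others 1.53 to 1.59). In neo-liver they were the acute phase median on array 2 (-0.53, others 0.29 to 0.33) and, on array 4, the periportal (-3.085, others -2.12 to -2.05) and urea cycle (-3.085, others -2.27 to -2.21) medians. Neo-liver levels were Alb (10.52, others 9.92 to 10.01) and Nr0b2 (-1.63, others 0.44 to 0.84) on array 1, and Gdf15 (4.36, others 4.76 to 4.84) and Krt19 (-2.83, others -2.01 to -1.94) on array 2. On array 4 they were Gls2 (2.08, others 4.25 to 4.66), Loxl1 (0.37, others -0.44 to -0.34) and Sult3a1 (6.42, others 6.79 to 6.83). Among probes without a gene symbol, used in no comparison, 1 was well above background on all neo-liver arrays and on no other array.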

How the results depend on the processing

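Mouse as a random block and omitting genes below background in both groups were chosen after the data were seen. Outside the settings that leave out 1 array, 3796 values of named genes and 2250 of lists kept their direction and their side of the threshold, 69 and 43 were no longer past it, 20 and 56 came past it, and 9 and 7 changed direction. On leaving out 1 array, 1798 and 1072 kept them, 112 and 19 were no longer past, and 5 and 19 came past. Of counts and shares, 125 stayed within 1.5 times or 1 SD and 18 moved, and on leaving out 1 array 59 stayed and 11 moved. With the replicate number as a block, which ties control livers to hosts by number alone, 4 lists came past the threshold, and with mouse as a random block 0 did. The kidney share lay between 24.2% and 34.5% over these alternatives, but was 45.9% or 12.2% by zone markers.

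Quantile normalization gave 2598 genes lower in neo-liver than in host liver, with Hnf4a at 0.077, and median centring gave 3243 higher in host liver than in control liver. The cause was not tested. Without a filter, 5503 genes were higher in neo-liver than in host kidney, and with probes above background on all arrays, 2012 were higher than in control liver and 1478 than in host liver, as other genes were tested. With only their arrays in the fit, 1293 genes were higher in host liver than in control liver, from fewer arrays. A threshold of 1 on the log2 scale, stricter by construction, left 2027 genes higher and 2102 lower than in host kidney, 1288 lower than in control liver, and 1714 higher and 637 lower than in host liver. For host liver against control liver it left 721 higher and 644 lower, with 533 and 304 shared with the changes of neo-liver.

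Without genes at least 2-fold higher in host kidney than in host liver, fewer genes were tested: 1240 were higher in neo-liver than in control liver and 478 than in host liver. The medians of the remaining bile duct genes were -0.80 and -1.12, and of the remaining podocyte genes -0.10 and -0.36. With the kidney share subtracted, 1537 genes were higher than in host liver, the bile duct median was -1.11 against control liver and -0.88 against host liver, and the Kupffer median of -0.31 tested in the opposite direction. Against control liver Krt7 was then at -0.23, Epcam at -0.083 and Emcn at -0.14, and against host liver Umod at -0.70, Lrp2 at -1.12, Krt7 at -0.68, Spp1 at -2.04 and Cd163, below background in both groups, at 0.31. None of these lists and genes was called. By construction, this subtraction lowers genes that kidney makes.

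Leaving out 1 array, host liver against control liver gave 1206 to 2233 genes higher and 1069 to 1930 lower, and the overlap with neo-liver changes was 698 to 743 higher and 659 to 738 lower, from fewer arrays. The counts of the other comparisons moved by less than 1.5 times. In all, 1031 genes were below background in both groups of host liver against control liver, 78 of them called, against 296 and 40 for neo-liver against control liver, 324 and 66 against host liver, and 11 and 3 against host kidney.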

Other observations

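All tests and named genes of this part were chosen after the results were seen. Genes higher in neo-liver than in host kidney, host liver and control liver alike numbered 132, of which 74 differed at least 2-fold from each, and 323 were lower than in all 3, of which 5 at least 2-fold. The 132 held 8 of 26 matrix and myofibroblast genes (Bgn, Col1a1, Col1a2, Col3a1, Col5a2, Lum, Timp1 and Vim). They held 4 of 24 stellate cell genes (Cygb, Hand2, Lum and Pdgfrb). Fisher's exact test gave adjusted p = 1.07e-09 and 0.000840 over the lists. These tests treat members as independent, whereas camera estimated correlations of 0.361 and 0.0996 within the 2 lists, and with them the matrix list was called in none of the 4 comparisons. Lum counts in both lists. The granulocyte genes Ngp, Ltf, Mpo, Camp, Cebpe, Chil3 and Ctsg, in no tested list, were among the 132 too. Their smallest differences from the other 3 groups were 3.45 to 2.20. The 132 held 2 of 20 myeloid inflammation genes (Fisher's exact test, adjusted p = 0.15) and 1 of 21 sinusoidal endothelial genes, Lyve1.

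Probes of Gpr174, a lymphocyte receptor gene, and Gdf6, a growth factor gene, were well above background on all 4 neo-liver arrays and no others. Against host liver they rose by 0.97 and 1.71 only, so absence elsewhere is not shown.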
